A study of Mus musculus with 6 samples.

How the data were processed

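RNA immunoprecipitation followed by sequencing (RIP-seq) was done on cultured mouse germ stem cells. An antibody pulls a protein out of a cell lysate and the RNA that comes with it is sequenced. Per the labels, the cells grew in a stem cell medium to which GDNF and FGF2 had been added (10 ng/ml of each), total RNA was taken, and libraries were read as 150 bp paired ends. The 6 libraries fall into 3 groups of 2: RNA pulled down with an antibody against IGF2BP1 (IGF2BP1 RIP), RNA pulled down with a control IgG (IgG RIP), and RNA that was not pulled down (input). No label says whether the 2 libraries of a group came from separate cultures.

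The authors deposited 1 table of 22564 protein-coding genes and 1 further line without values, with a count column and an FPKM column for each library. The deposited count columns are read here as estimated counts of fragments per gene, each multiplied by 1 factor per library. This was tested on the values: between 92.8% and 94.1% of the values above 0 of each library are whole multiples of a single step, within a tolerance of 0.01, and the steps lie between 0.954 and 1.03. The step was divided out and the result rounded to give fragments. The deposited FPKM columns, as made by the authors, carry the name of fragments per kilobase of transcript scaled to library size. They were used in 2 alternatives and to gauge transcript length. Their totals ran with depth, at 396995 and 423117 in IGF2BP1 RIP, 383600 and 370158 in IgG RIP, and 252152 and 259949 in input. They therefore do not appear scaled to depth, and uncentred FPKM values carry differences in depth between the groups. The length index of a gene is the median over libraries, where it has at least 10 fragments, of its deposited count over its FPKM, a relative measure of the transcript length the authors used. The column named length in the deposited table is of another kind: it equals the span of the locus from start to end, not the length of a transcript. Per the submitters' processing notes, FastQC, cutadapt 1.9.3 and the mouse build mm39 were used. The aligner and the counting tool are not given in the sources used here. Of 20874 genes matched by gene number to an annotation of the older mouse build GRCm38 (mm10), 99.909% overlap their GRCm38 position, so the coordinates printed here are those of the file, read as GRCm38. Exons and untranslated regions were not analysed here. In the table, 5875 genes carry exactly the same locus span as another gene, 162 symbols are repeated, and 5353 genes are at 0 in all libraries. The assignment of fragments to genes that share a span is uncertain, as it is for multigene families such as histones.

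Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM normalization, the quasi-likelihood test). All 6 libraries entered 1 model with a term for each of the 3 groups, which leaves 3 residual degrees of freedom, and no batch term was used because the labels name no batch. This is called the pooled test. P-values were adjusted over the 12053 genes tested by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Fold changes are log2 values, and levels are CPM (fragments scaled to a common library size) after TMM, with the SD over 2 libraries. The 3 comparisons were IGF2BP1 RIP against IgG RIP, IGF2BP1 RIP against input and IgG RIP against input. Genes called higher in IGF2BP1 RIP than in both controls were counted as the overlap of the first 2 comparisons. The spread between the libraries of a group was expressed as an index: the median over genes of the squared difference of the 2 libraries, scaled to equal size, over their sum, divided by the value that counting noise gives. An index of 1 is counting noise alone.

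Lists of genes were written before the data were examined, as were the comparisons, the tests, the first set of other settings and the rule for named genes. The 28 lists are the IGF2BP family, published IGF2BP targets, stem cell self-renewal, spermatogonial differentiation, meiosis and spermatids, piRNA and germ granules, Sertoli and Leydig markers, fibroblast and feeder markers, immune, blood and endothelial markers, GDNF, PI3K and MAPK signalling, cell cycle, apoptosis and p53, Wnt, Notch and TGF-beta, adhesion and cytoskeleton, m6A machinery, RNA stability factors, translation factors, chromatin regulators, endoplasmic reticulum and folding, cholesterol synthesis, glycolysis, nuclear non-coding RNAs, the mitochondrial genome, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, nuclear genes of oxidative phosphorylation, replication-dependent histones, and Zfp zinc fingers. The list of published targets was drawn from knowledge of other, mostly human, cells and not from these libraries. Nuclear non-coding RNAs have 0 members in the table and could not be tested, which leaves 27 lists of at least 3 tested members. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera again with the correlation estimated from the data, and with fry. Adjusted p-values of lists are over the 27 lists of a comparison. The lists share some members: Vim stands among both the Sertoli and the fibroblast markers, and Pabpc1 among the published targets, the RNA stability factors and the translation factors.

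Named genes follow a rule. In each comparison of IGF2BP1 RIP with a control they are the 10 genes with the largest positive and the 10 with the largest negative fold change among called genes whose libraries do not overlap between the groups and whose mean level is at or above the median of tested genes. For IgG RIP against input the number is 5 each way. Predicted models and pseudogenes were left out. From each list come the 2 members with the smallest adjusted p in each direction, and Igf2bp1, Igf2bp2 and Igf2bp3 always. Of the genes higher than in both controls, the 10 with the largest value of the smaller fold change were taken, at the same level. Any gene named outside this rule is said to be so. Some genes that the rule names are not reported.

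The total of fragments on listed genes ran from 1639250 to 2836942 per library. A count of 0 allows up to 3 fragments, which is between 1.06 and 1.86 CPM. Such limits cover counting error only, since fragments amplified by PCR are not independent molecules.

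Other settings fixed beforehand were DESeq2-style size factors, no composition factor, no filter on low counts, a stricter filter (at least 50 fragments in at least 2 libraries), the Wald test of DESeq2 1.42.0, limma-voom, a model with only the 2 groups compared, the replicate number as a block, each library left out in turn, and a fold change of at least 2. Another 4 were chosen after seeing the data: limma-voom with a weight for each group, limma on log2 of the authors' FPKM plus 1, the same after centring each library on its median, and a test of only the genes that share no locus span. The centred FPKM values were added after the uncentred ones were seen to shift the median gene and to reverse several results. Both are reported.

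The tests were tried on simulated counts of 12053 genes at the depth of the libraries, with 200 changed genes and 3 runs. The changed genes were drawn only from those above the median level, so the shares recovered hold for such genes. With the spread of each group as in the data, the pooled test recovered 91.0% of the genes changed 4-fold and 50.3% of those changed 2-fold between IGF2BP1 RIP and IgG RIP, and 7.42% of its calls were false. Between IGF2BP1 RIP and input it recovered 90.7% and 45.0%, and 0% were false. A test on the 2 groups alone recovered 72.7% and 26.7% in the first comparison, with 0% false calls, and 100% and 97.3% in the second, with 2.79% false. Between IgG RIP and input the pooled test recovered 81.7% and 46.7%, with 3.99% false, and the 2-group test 71.7% and 27.3%, with 0% false. With no changed gene, the pooled test made 0 calls in these runs, by edgeR. With 1 spread for all groups, the pooled test recovered between 96.0% and 97.7% of the genes changed 4-fold, with between 4.38% and 7.34% false calls. Weights per group gave 23.1% false calls between IGF2BP1 RIP and IgG RIP. In simulated data without change and with the spread of each group, camera at the preset correlation called 1 of the 27 lists over 3 runs against IgG. It called 0 in IGF2BP1 RIP against input and 4 in IgG RIP against input. The simulated genes were drawn independently, so these runs cannot show how often camera calls lists of correlated genes. The correlation estimated against IgG RIP was 0.063 for ribosomal proteins and 0.060 for histones.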

Results

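RNA pulled down with an antibody against the RNA-binding protein IGF2BP1 was sequenced from cultured mouse germ stem cells, next to 2 kinds of control. There were 2 libraries of IGF2BP1 RIP, 2 of IgG RIP and 2 of input. The fragments on protein-coding genes numbered 2793425 and 2836942 in IGF2BP1 RIP, 2558673 and 2723449 in IgG RIP, and 1639250 and 1693165 in input. Genes with at least 1 fragment numbered 15022 and 14989 in IGF2BP1 RIP, 13379 and 13096 in IgG RIP, and 15047 and 15089 in input. Genes of the mitochondrial genome took 4.85% and 5.36% of the fragments in IGF2BP1 RIP, 3.14% and 3.80% in IgG RIP, and 4.64% and 4.21% in input. As no label says that replicates came from separate cultures, the p-values measure only the spread between these libraries.

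The transcript of the antibody's own target, Igf2bp1 (ENSMUSG00000013415, GRCm38 chromosome 11, 95957163 to 96005940), was present in every library. Its level was 454.6 and 421.6 CPM in IGF2BP1 RIP, 394.6 and 450.1 CPM in IgG RIP, and 369.6 and 355.4 CPM in input, with means of 438 ± 23.3, 422 ± 39.2 and 362 ± 10.1 CPM (SD, n = 2). The log2 fold change of IGF2BP1 RIP was 0.05 ± 0.10 (SE) over IgG RIP (adjusted p = 0.787, edgeR quasi-likelihood test) and 0.27 ± 0.10 over input (adjusted p = 0.166). With only IGF2BP1 RIP and input in the model the second difference passed the threshold (adjusted p = 0.00489), and over all other settings its adjusted p ran from 0.00102 to 0.684. Of the related genes, Igf2bp2 had fold changes of 0.55 over IgG RIP and 0.42 over input, and Igf2bp3, which shares its locus span with another gene, had 0.48 and 0.03. None of the 3 family members was called in either comparison by the pooled test. Igf2bp2 over input also passed with only those 2 groups in the model (adjusted p = 0.0152, from 0.00840 to 0.894 over all other settings). Igf2bp3 over IgG RIP was 1.53 without IgG replicate 1, where it passed (adjusted p = 4.15e-05), and -0.12 without IgG replicate 2, with the adjusted p up to 0.843 in other settings. Igf2bp2 over IgG RIP passed without IgG replicate 1 (0.37) and without IgG replicate 2 (0.76), with an adjusted p from 5.61e-04 to 0.563 over all other settings. Igf2bp1 over IgG RIP turned to -0.006 without IGF2BP1 replicate 1 and to -0.038 without IgG replicate 1. Over all other settings its fold change ran from -0.038 to 0.74 over IgG RIP and from 0.23 to 1.35 over input. The 1.35 is from the authors' FPKM.

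The 2 IgG libraries differed from each other far more than the libraries of the other groups did. The spread index was 14.2 in IgG RIP, 1.73 in IGF2BP1 RIP and 1.32 in input, where 1 is counting noise alone, and the biological coefficient of variation was 49.7%, 7.76% and 6.76%. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.979 within IGF2BP1 RIP, 0.969 within input and 0.849 within IgG RIP. Each IgG library correlated more with the IGF2BP1 libraries (0.882 to 0.884) and with the input libraries (0.874 to 0.881) than with the other IgG library. IgG RIP held 286 genes with a single fragment in each library, against 938 and 967 in IGF2BP1 RIP and 1367 and 1320 in input. The pooled test averages these unlike spreads to 25.2%, so the counts of genes are given beside those of a test on the 2 groups alone.

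**Figure D1:**
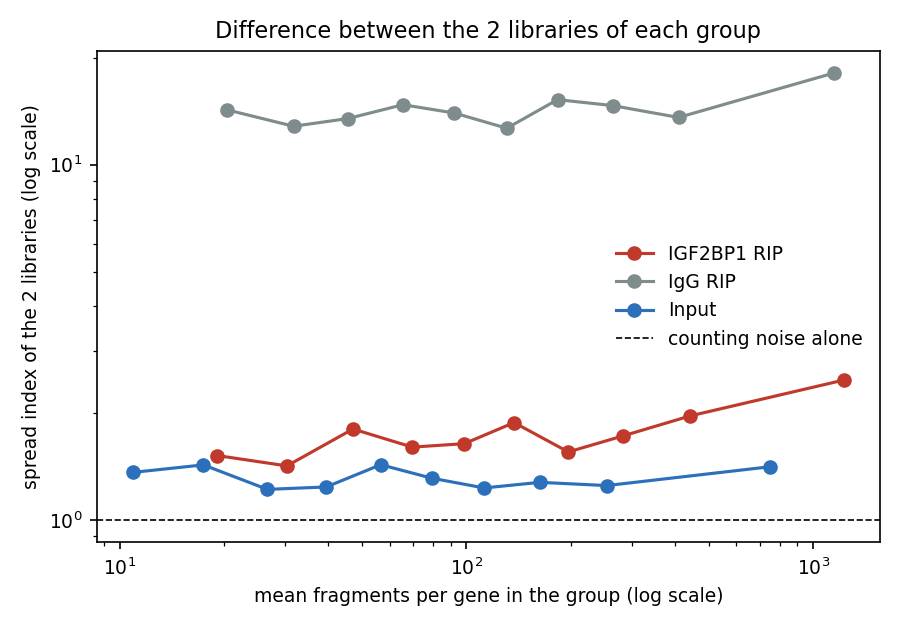
Spread index of the 2 libraries of each group (vertical, log scale, 1 is counting noise) against the mean number of fragments per gene (horizontal, log scale), each point being the median of a bin of genes by input level. The IgG points lie between 12.7 and 18.1 and the input points between 1.22 and 1.43.

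The comparison of IGF2BP1 RIP with IgG RIP asks which RNAs took a larger or smaller share with the IGF2BP1 antibody than with a non-specific antibody. The values are scaled to library size, so the amounts of RNA brought down were not compared. Prkab1, a regulatory subunit of the energy sensor AMPK (ENSMUSG00000029513, chromosome 5, 116009316 to 116024508), stood at 82.8 ± 4.18 CPM in IGF2BP1 RIP and 24.3 ± 9.53 in IgG RIP (SD, n = 2), a log2 fold change of 1.77 ± 0.29 (SE). Suclg1, a subunit of the citric acid cycle enzyme succinyl-CoA ligase (ENSMUSG00000052738, chromosome 6, 73248382 to 73276911), stood at 96.6 ± 6.76 against 35.1 ± 1.46 CPM, a log2 fold change of 1.46 ± 0.18. In the opposite direction, the histone gene Hist1h2bq (ENSMUSG00000069307, chromosome 13, 21806412 to 21810199) stood at 40.9 ± 3.05 against 286 ± 34.7 CPM (-2.80 ± 0.16), and Ttn, which encodes titin (ENSMUSG00000051747, chromosome 2, 76703980 to 76982547), at 52.1 ± 5.25 against 290 ± 24.9 CPM (log2 fold change -2.47 ± 0.14). The growth factor transcript Igf2, from which the IGF2BP family takes its name (ENSMUSG00000048583, chromosome 7, 142650766 to 142670356), was lower in IGF2BP1 RIP, at 253 ± 4.31 against 757 ± 1.28 CPM (log2 fold change -1.58 ± 0.07).

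Besides Prkab1 and Suclg1, the 10 named genes that were higher in IGF2BP1 RIP were Hmgb1 (log2 fold change 2.39), Gmeb1 (1.92), the ribosomal protein gene Rpl15 (1.89), Ppme1 (1.67), the cell cycle inhibitor Cdkn2a (1.60), the mitotic kinase Aurka (1.52), Rnf128 (1.48) and Mns1 (1.47). Hmgb1, Rpl15 and Mns1 share their locus span with another gene. Of the 10, only Prkab1 was also called higher than in input. Hmgb1 and Rnf128 were called lower in IgG RIP than in input. The adjusted p of these 10 ran from 0.00650 to 0.0315 in the pooled test, and 2 of them, Rpl15 and Suclg1, also passed in the test on the 2 groups alone. The 10 that were lower include, besides Hist1h2bq and Ttn, mt-Nd6 (-2.97), Hist1h2bg (-2.72), the folate hydrolase Ggh (-2.67), the chemokine Ccl7 (-2.61), Hist1h2bn (-2.60), Wfdc17 (-2.50) and Hist1h4n (-2.40). Of these, mt-Nd6, Hist1h2bg and Ccl7 share a span. The adjusted p of the 10 ran from 4.27e-04 to 0.00615, and 9 passed in the test on the 2 groups alone, all but mt-Nd6.

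Among the 12053 genes tested, 396 were higher and 456 lower in IGF2BP1 RIP than in IgG RIP at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), of which 139 and 226 differed at least 2-fold. Of the called genes, 108 of the higher and 127 of the lower share a locus span. The 2 libraries of each group did not overlap in 52.0% of genes, where chance gives 33.3%. The test on the 2 groups alone called 37 higher and 107 lower, 35 and 107 of them among the calls of the pooled test. The counts depend on each library: without IgG replicate 1 they were 2980 and 2681, without IgG replicate 2 they were 2801 and 2569. Without IGF2BP1 replicate 1 they were 10 and 39, without IGF2BP1 replicate 2 they were 8 and 38. Without input replicate 1 they were 37 and 106, and without input replicate 2 they were 37 and 108. On the authors' FPKM, where the median gene lay 0.11 higher in IGF2BP1 RIP, the split was 229 higher and 134 lower.

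Replication-dependent histone mRNAs, which end without a poly(A) tail, were lower in IGF2BP1 RIP than in IgG RIP as a group. Of 68 tested, 0 were higher, 31 lower and 37 not called, with 0 and 38 adjusted over the list alone and 0 and 14 in the test on the 2 groups alone, and the median log2 fold change was -1.01. The list passed camera at the preset correlation (adjusted p = 1.01e-30) and not with the correlation estimated (adjusted p = 0.172 with an estimated correlation). Hist1h4d stood at 399 ± 11.3 CPM against 1378 ± 226 in IgG RIP (log2 fold change -1.79). Of 87 cytosolic ribosomal protein genes, 4 were higher, 32 lower and 51 not called (5 and 45 adjusted over the list alone, 2 and 10 in the test on the 2 groups alone), with a median of -0.48 and an adjusted p of 4.15e-15 (adjusted p = 0.196 with an estimated correlation). The ribosomal median was -0.28 without IgG replicate 1 and -0.18 on the authors' FPKM. Among them Rps3 was lower (-1.16), Rpl12 was lower (-1.36) and Rpl4 was higher (0.51). Of 40 chromatin regulators, 0 were higher and 7 lower (2 and 11 adjusted over the list alone, 0 and 6 in the test on the 2 groups alone), with a median of -0.11 (0.01 on the authors' FPKM) and an adjusted p of 6.36e-04 (adjusted p = 0.196 with an estimated correlation). That chromatin call was lost without IgG replicate 1 (median -0.18) and without IgG replicate 2 (median -0.18). It was also lost on FPKM (adjusted p = 0.203) and on centred FPKM (median -0.02, adjusted p = 0.163), with a range from 2.69e-04 to 0.203 over all other settings. The histone methyltransferase genes Kmt2a (-1.23) and Kmt2d (-1.14) were among the lower ones. Among all tested genes, the highest of 10 classes by length index had a median of -0.23 in this comparison. No lists matched on length were drawn for chromatin regulators, so a part of length in their difference was not tested. Of 19 piRNA and germ granule genes, 3 were higher and 0 lower (5 and 0 adjusted over the list alone, 0 and 0 in edgeR on the 2 groups alone), with a median of 0.20 and an adjusted p of 0.0391 (adjusted p = 0.494 with an estimated correlation). They included Tdrd1 at 339 ± 21.1 against 207 ± 26.6 CPM (log2 fold change 0.71) and Mael (0.46). The piRNA median was 0.34 without IgG replicate 1 and 0.38 on the authors' FPKM. The list was not called without IgG replicate 2 (median 0.17), with the stricter filter on low counts (adjusted p = 0.0721) or on centred FPKM (adjusted p = 0.0554). Over all other settings its adjusted p ran from 0.0105 to 0.434.

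Camera did not call the other lists against IgG RIP. Fry, which asks whether the genes of a list move on balance and does not compare them with other genes, passed 8 of them. They are self-renewal (adjusted p = 0.00494), cholesterol synthesis (0.0119), differentiation (0.0191), cell cycle (0.0191), the IGF2BP family (0.0272) and translation factors (0.0461) in the higher direction, and Wnt, Notch and TGF-beta (0.0435) and adhesion (0.0461) in the lower. Of 34 stem cell self-renewal genes, 3 were higher and 0 lower (4 and 0 adjusted over the list alone), among them the GDNF receptor Ret at 522 ± 14.5 against 384 ± 21.7 CPM (log2 fold change 0.44) and the transcription factor Etv5 at 260 ± 12.4 against 180 ± 7.90 CPM (0.53). Neither Ret nor Etv5 passed in the test on the 2 groups alone (adjusted p = 0.108 and 0.106), and over the other settings their adjusted p ran from 5.31e-05 to 0.277 and from 6.23e-05 to 0.310. Of 17 spermatogonial differentiation genes, 2 were higher and 0 lower (3 and 0 adjusted over the list alone), namely Dmrt1 (0.93) and Uhrf1 (0.53). Of 23 meiotic and spermatid genes, Mael was higher and Tex15 lower (-1.35), with 3 and 1 adjusted over the list alone. Of 37 published IGF2BP targets, 3 were higher and 4 lower (7 and 7 adjusted over the list alone), including Pabpc1, the poly(A)-binding protein gene, at 3659 ± 6.25 against 2087 ± 151 CPM (0.81), Actb (0.58), Igf2 (-1.58) and Rac1 (-0.92). The median of the published targets was 0.12 and the mean 0.03, while camera's direction was down (adjusted p = 0.970).

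Of 48 cell cycle genes, 6 were higher and 4 lower against IgG RIP (10 and 5 adjusted over the list alone), among them Bub1b (0.59), Cenpf (-0.43) and Cdk4 (-1.02). Of 40 adhesion and cytoskeleton genes, 4 were higher and 6 lower (6 and 7 adjusted over the list alone), with the dynein heavy chain Dync1h1 at 826 ± 9.75 against 2137 ± 80.1 CPM (-1.37) and Dst at -1.58. RNA stability factors gave 5 higher and 3 lower of 44 (7 and 8 adjusted over the list alone), with Ptbp1 (0.67) and Ago3 (-0.92), and translation factors 4 and 1 of 36 (7 and 4), with Eif3b (0.87) and Eif4a2 (-0.81). In the m6A machinery Hnrnpa2b1 was higher (0.77) and Rbm15 lower (-0.77) of 17 (3 and 2 adjusted over the list alone). GDNF, PI3K and MAPK signalling gave 2 and 0 of 47 (4 and 1). Wnt, Notch and TGF-beta gave Smad2 (0.58) and Smad7 (-1.09) of 36 (1 and 1), apoptosis and p53 1 and 0 of 28 (1 and 0), and endoplasmic reticulum and folding Pdia6 (0.96) and Copa (-0.41) of 33 (2 and 3). Cholesterol synthesis gave Fdft1 (1.08) alone of 21 (4 and 3), glycolysis Eno1 (0.53) alone of 19 (2 and 0), and the IGF2BP family 0 and 0 of 3 (0 and 0). Of 11 genes of the mitochondrial genome, mt-Cytb (1.03), mt-Nd5 (0.63) and mt-Nd2 (1.05) were higher and mt-Nd6 lower, with 3 and 1 adjusted over the list alone, a median of 0.32 and a mean of -0.23. Mitochondrial ribosomal proteins gave 2 and 1 of 73 (2 and 1), nuclear genes of oxidative phosphorylation 3 and 6 of 74 (6 and 12) and Zfp zinc fingers 3 and 10 of 274 (2 and 8), with Zfp710 (0.64) and Zfp292 (-1.70).

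The 3 lists of markers of other cells were not called against IgG RIP, which does not mean that such RNA was absent. Enough fragments for a test were found for 29 of 29 fibroblast, 14 of 20 immune and 4 of 19 Sertoli and Leydig markers. Cd68, for example, stood at 161 ± 5.22 CPM in input. From which cells the called RNAs came was not tested. Fibroblast and feeder markers gave 0 higher and 2 lower of 29 (1 and 3 adjusted over the list alone), Prrx1 (-1.67) and Thbs1 (-0.38). Immune, blood and endothelial markers gave 2 and 1 of 14 (3 and 1), C1qc (0.79), Cd68 (0.57) and Fcer1g (-1.91), and Sertoli and Leydig markers 0 and 0 of 4 (1 and 0). Their adjusted p in camera was 0.533, 0.499 and 0.654. The immune list nonetheless had a median of 0.59, the highest of the 27 lists in this comparison, and its mean relative to input was -1.08 in IgG replicate 1 and 0.09 in IgG replicate 2, against -0.01 and -0.09 in IGF2BP1 RIP. Of the list members named against IgG RIP, Rpl12, Cdk4, Ptbp1, Eif4a2, Pdia6, Copa, Fdft1, mt-Cytb and mt-Nd5 share a locus span, so their fragments are less surely assigned.

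Most calls among these lists do not hold in the test on the 2 groups alone, in which edgeR called 0 higher and 0 lower in self-renewal, differentiation, cell cycle and oxidative phosphorylation. It called 1 and 0 in RNA stability factors, 3 and 0 in translation factors, 1 and 4 in adhesion, 2 and 2 in published targets, 3 and 0 in the mitochondrial genome and 0 and 2 in Zfp zinc fingers. The list members named against IgG RIP that passed there are Hist1h4d, Rps3, Rpl12, Rpl4, Kmt2a, Kmt2d, Tex15, Pabpc1, Actb, Igf2, Rac1, Dync1h1, Dst, Eif3b, Fdft1, mt-Cytb, mt-Nd5, mt-Nd2, Zfp292 and Fcer1g. Those that did not include Tdrd1, Mael, Ret, Etv5, Dmrt1, Uhrf1, Bub1b, Cdk4 and Ptbp1.

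The comparison of IGF2BP1 RIP with input asks how the pulled-down RNA differed from the RNA present in the cells. Sap130, a subunit of a histone deacetylase complex (ENSMUSG00000024260, chromosome 18, 31634371 to 31723061), stood at 380 ± 8.96 CPM in IGF2BP1 RIP and 132 ± 4.71 in input (SD, n = 2), a log2 fold change of 1.53 ± 0.13 (SE). Med15, a Mediator subunit (ENSMUSG00000012114, chromosome 16, 17651221 to 17722930), stood at 292 ± 4.25 against 110 ± 0.994 CPM (1.41 ± 0.17). Tmem38b, an ion channel gene of the endoplasmic reticulum (ENSMUSG00000028420, chromosome 4, 53826045 to 53862019), was lower, at 31.7 ± 0.413 against 664 ± 29.7 CPM (log2 fold change -4.39 ± 0.21). So was Fth1, the ferritin heavy chain (ENSMUSG00000024661, chromosome 19, 9980600 to 9985111), at 454 ± 0.323 against 2099 ± 2.67 CPM (-2.21 ± 0.08), and the ribosomal stalk gene Rplp1 (ENSMUSG00000007892, chromosome 9, 61913284 to 61914538), at 105 ± 6.55 against 461 ± 16.7 CPM (-2.13 ± 0.11).

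The other named genes higher than in input were Prkab1 (log2 fold change 1.37), Mospd3 (1.32), the Polycomb gene Phc1 (1.24), Paxip1 (1.23), Zmiz2 (1.21), Mkl1 (1.17), the co-chaperone gene Bag3 (1.16) and Cherp (1.14). The others lower than in input were mt-Nd6 (-4.22), Wfdc17 (-3.46), Tmsb4x, which encodes the actin-binding thymosin (-3.04), Ggh (-2.40), Rps15a (-2.37), Cox17 (-2.24) and Lars2 (-2.11). The adjusted p ran from 0.00197 to 0.0412 for the higher 10 and from 1.29e-04 to 0.00808 for the lower 10, and all 20 also passed in the test on the 2 groups alone. Mkl1, Cherp, mt-Nd6 and Cox17 share a locus span. Igf2 was again lower, at 253 ± 4.31 against 743 ± 17.4 CPM (log2 fold change -1.55 ± 0.08).

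At an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 266 genes were higher and 454 lower in IGF2BP1 RIP than in input, of which 24 and 222 differed at least 2-fold, and 72 and 117 share a locus span. The libraries did not overlap in 66.8% of genes, where chance gives 33.3%. The test on the 2 groups alone, without the IgG libraries, called 1925 higher and 2169 lower, which include all 266 and 454. Without IgG replicate 1 the counts were 2021 and 2075 and without IgG replicate 2 they were 1947 and 2153. Without IGF2BP1 replicate 1 they were 1 and 19, without IGF2BP1 replicate 2 they were 4 and 30, without input replicate 1 they were 2 and 14, and without input replicate 2 they were 1 and 20. On the authors' FPKM the median gene lay 0.68 higher in IGF2BP1 RIP and the split was 3248 higher and 69 lower.

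Cytosolic ribosomal protein mRNAs showed the most uniform difference from input among the lists. Of 87 tested, 0 were higher, 55 lower and 32 not called (0 and 73 adjusted over the list alone), and 77 were lower in the test on the 2 groups alone. Their median log2 fold change was -1.0 (-0.05 on the authors' FPKM) and the adjusted p 2.57e-76 (adjusted p = 0.0580 with an estimated correlation). Of 68 histone mRNAs, 0 were higher and 19 lower (0 and 40 adjusted over the list alone). In the test on the 2 groups alone, 0 of 66 were higher and 55 lower. The histone median was -1.04 (-0.07 on the authors' FPKM) and the adjusted p 8.24e-24 (adjusted p = 0.0941 with an estimated correlation). Of 74 nuclear genes of oxidative phosphorylation, 0 were higher and 14 lower, Cox6c (-1.58) and Ndufb9 (-1.44) among them. The counts were 2 and 30 adjusted over the list alone, and 8 and 50 in the test on the 2 groups alone. The list median was -0.80, or 0.12 on the authors' FPKM, where the median gene lay at 0.68. Its adjusted p was 2.88e-12 (adjusted p = 0.0941 with an estimated correlation). Of 73 mitochondrial ribosomal protein genes, 0 were higher and 2 lower, Mrpl33 (-1.71) and Mrps21 (-2.0). The counts were 0 and 0 adjusted over the list alone, and 0 and 19 in the test on the 2 groups alone. This list had a median of -0.31 (0.50 on the authors' FPKM) and an adjusted p of 0.0298 (adjusted p = 0.205 with an estimated correlation). This last call was lost without IGF2BP1 replicate 2 (median -0.26), with the stricter filter on low counts (adjusted p = 0.137), on FPKM (0.133), on centred FPKM (0.137) and among genes sharing no locus span (0.178). Over all settings this adjusted p ran from 0.00278 to 0.178.

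Chromatin regulators and 3 of the germline lists had medians above input, with few germline genes called singly by the pooled test. The test on the 2 groups alone called 9 higher and 3 lower of 30 self-renewal genes and 9 and 2 of 16 differentiation genes. It called 9 and 2 of 18 piRNA genes and 21 and 3 of 40 chromatin regulators, beside 1925 and 2169 of all 11338 genes. Of 40 chromatin regulators, 10 were higher and 2 lower (16 and 2 adjusted over the list alone), with a median of 0.26 and an adjusted p of 9.09e-06 (adjusted p = 0.0941 with an estimated correlation). Their mean relative to input was 0.22 and 0.21 in the IGF2BP1 libraries and higher, at 0.43 and 0.41, in the IgG libraries. Over the other settings the median ran from 0.19 to 0.98 for chromatin regulators and from 0.17 to 0.91 for self-renewal. It ran from 0.33 to 1.06 for differentiation and from 0.19 to 0.91 for piRNA genes. The remodeller gene Arid1a (0.76) and the demethylase gene Kdm6b (0.66) were higher, and Suz12 (-0.56, against 0.21 on the authors' FPKM) and Kmt2a (-0.40, against 0.29 on FPKM) were lower. Of 17 spermatogonial differentiation genes, Sohlh2 (0.65) and the retinoic acid receptor gene Rara (0.83) were higher and 0 lower (5 and 1 adjusted over the list alone), with a median of 0.35 and an adjusted p of 0.0161 (adjusted p = 0.212 with an estimated correlation). Of 34 self-renewal genes, 3 were higher and 1 lower (4 and 1 adjusted over the list alone), with a median of 0.23 and an adjusted p of 0.0304 (adjusted p = 0.212 with an estimated correlation). They were led by Etv5 (0.73) and Ret (0.51), and the lower one was Dazl (-0.46, against 0.36 on FPKM). Of 19 piRNA and germ granule genes, Tdrd1 (0.84) and Tdrd5 (0.53) were higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.31 and an adjusted p of 0.0476 (adjusted p = 0.346 with an estimated correlation). The self-renewal call was lost without input replicate 1 (median 0.17), and the piRNA call without IGF2BP1 replicate 2, without input replicate 1 and without input replicate 2 (median 0.31 in each). In the test on the 2 groups alone neither the self-renewal nor the piRNA call held (adjusted p = 0.0618 for each). Over all other settings the adjusted p ran from 1.47e-04 to 0.139 for self-renewal and from 0.0107 to 0.108 for piRNA. With the stricter filter on low counts these calls of self-renewal (adjusted p = 0.139), differentiation (0.1004, the highest over its settings, from 0.00278, and not called on the authors' FPKM either) and piRNA genes (0.108) were lost. Of 23 meiotic and spermatid genes, Tex14 was higher (0.44), and Sycp1 (-1.27) and Tex15 (-1.31) were lower (2 and 3 adjusted over the list alone), with a median of -0.06 and an adjusted p of 0.375.

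Of 37 published IGF2BP targets, 4 were higher and 5 lower than in input (9 and 8 adjusted over the list alone), with a median of -0.03 and an adjusted p of 0.525. Hmga1 (0.96) and Pabpc1 (0.38) were higher, and Igf2 (-1.55) and Ybx1 (-1.05) lower. Of 36 translation factors, 3 were higher and 7 lower (7 and 10 adjusted over the list alone), with an adjusted p of 0.0928. In the test on the 2 groups alone the genes higher and lower were 10 and 9 for published targets and 8 and 14 for translation factors. They were 5 and 7 for fibroblast markers, 2 and 3 for 13 immune markers, and 5 and 5 for 21 meiotic and spermatid genes. Fibroblast markers gave 0 and 2 of 29 (0 and 2 adjusted over the list alone), Sparc (-0.45, against 0.37 on FPKM) and Prrx1 (-1.22), and immune markers Cd68 (1.06) alone of 14 (1 and 0). The immune list had a median of -0.19 and a mean of -0.10 while camera's direction was up (adjusted p = 0.571). Fry alone passed cell cycle (adjusted p = 0.00680), cholesterol synthesis (0.00872) and the IGF2BP family (0.0213) in the higher direction. In the lower direction it alone passed apoptosis and p53 (0.0230), meiosis (0.0297), translation factors (0.0297) and endoplasmic reticulum (0.0359). It did not pass piRNA genes (0.0536). Cox6c, Mrpl33, Mrps21 and Hmga1 share a locus span.

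**Figure D2:**
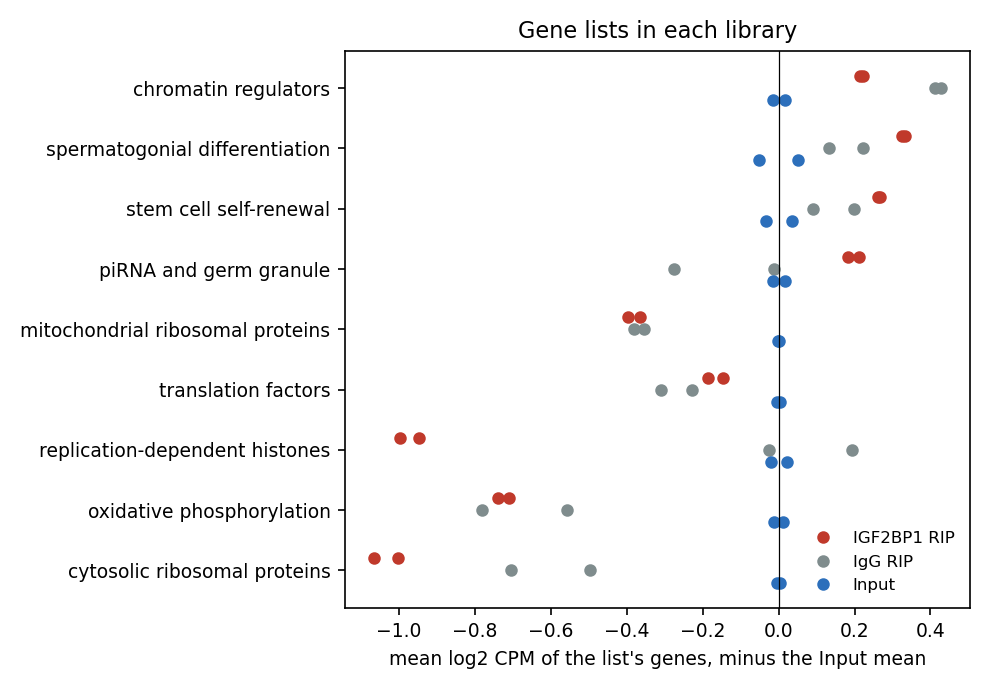
Mean log2 CPM of the genes of 9 lists in each of the 6 libraries, minus the mean of the input libraries (horizontal, log2 units), with 1 point per library. The IGF2BP1 libraries lie at -1.0 and -1.07 for cytosolic ribosomal proteins and at -0.95 and -1.0 for histones, where the IgG libraries lie at -0.02 and 0.19.

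Genes higher in IGF2BP1 RIP than in both controls were counted as the overlap of the first 2 comparisons. Prkab1 led them, with log2 fold changes of 1.77 over IgG RIP and 1.37 over input, followed by the glucose-6-phosphate dehydrogenase gene G6pdx (1.32 and 1.03), which shares a locus span. The guidance receptor gene Neo1 (0.99 and 0.99), Sap130 (0.91 and 1.53), Wac (0.86 and 0.95), Bcas3 (0.98 and 0.83), Med15 (0.82 and 1.41), the phosphatase subunit gene Ppp2r5d (0.99 and 0.82), the coactivator gene Ncoa6 (0.81 and 1.08) and Dcakd (0.94 and 0.79) completed the 10 named. Ppp2r5d and Dcakd share a span. Among the germline genes, Ret, Etv5 and Tdrd1 were higher than in both controls, with Ret at 522 ± 14.5 CPM in IGF2BP1 RIP, 384 ± 21.7 in IgG RIP and 366 ± 8.68 in input (SD, n = 2).

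In total 70 genes were higher than in both controls, 19 of which share a locus span, and 2 of the 70, Prkab1 and G6pdx, at least 2-fold in both. Independent lists of these sizes would share 8.74 genes, but both comparisons use the same IGF2BP1 libraries, so part of the overlap can come from those. Tests on 2 groups at a time called 22 genes higher than both controls, 13 of them among the 70. These 13, named after their values were seen, are Cct2, Fdft1, Gpnmb, Pabpc1, Pcbp1, Ssbp3, Stip1, Tomm34, Ubap1, Ubap2l, Zfr, mt-Nd2 and mt-Nd5, and 0 of the 10 genes named above are among them, since each missed the threshold against IgG RIP in edgeR with 2 groups. Without IgG replicate 1 the count was 777 and without IgG replicate 2 it was 802, while without any 1 of the other 4 libraries (IGF2BP1 replicate 1 or 2, input replicate 1 or 2) it was 1. In the other direction 185 genes were lower than in both controls, 75 of them at least 2-fold and 51 sharing a span, against 17.2 for independent lists, which these are not, as they share the IGF2BP1 libraries too.

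**Figure D3:**
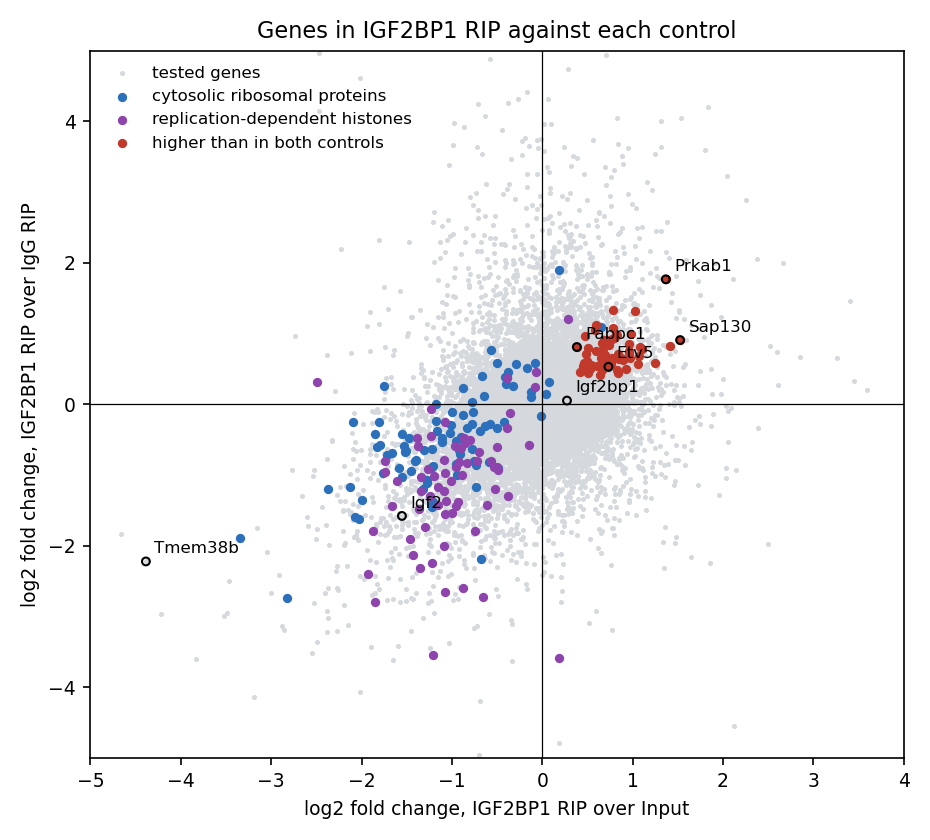
Log2 fold change of each of 12053 genes in IGF2BP1 RIP over input (horizontal) and over IgG RIP (vertical), with cytosolic ribosomal protein genes, replication-dependent histone genes and the 70 genes higher than in both controls in colour; 79 genes lie outside the axes. Prkab1 lies at 1.37 and 1.77, Igf2 at -1.55 and -1.58 and Igf2bp1 at 0.27 and 0.05.

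The comparison of IgG RIP with input measures how the shares of RNAs differed after a pull-down without the IGF2BP1 antibody. Tagln2, an actin-binding protein gene (ENSMUSG00000026547, chromosome 1, 172500047 to 172507380), stood at 316 ± 37.97 CPM in IgG RIP and 89.7 ± 0.344 in input (SD, n = 2), a log2 fold change of 1.82 ± 0.15 (SE). Arhgap1 (2.26), Hist1h2bg (2.06), Pag1 (1.79) and Scamp3 (1.78) were also higher, and Tmem38b (-2.16), Hmgb1 (-2.11), the respiratory chain gene Cox7a2l (-2.09), Rnf128 (-2.03) and Rps21 (-2.01) were lower. Hist1h2bg and Hmgb1 share a locus span. Adjusted p ran from 0.00302 to 0.0449 for the higher 5 and from 0.00302 to 0.0407 for the lower 5, and 3 of each also passed in the test on the 2 groups alone.

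Cytosolic ribosomal protein mRNAs were lower in IgG RIP than in input as well. Of 87, 2 were higher and 36 lower (3 and 50 adjusted over the list alone), with a median of -0.60 (0.01 on the authors' FPKM, where the median gene lay at 0.56) and an adjusted p of 2.31e-18 (adjusted p = 0.227 with an estimated correlation). Of 74 oxidative phosphorylation genes, 1 was higher and 17 lower (2 and 28 adjusted over the list alone), with a median of -0.57 (0.04 on the authors' FPKM) and an adjusted p of 2.70e-07 (adjusted p = 0.253 with an estimated correlation). Of 36 translation factors, 0 were higher and 7 lower (3 and 14 adjusted over the list alone), with a median of -0.37 (0.29 on the authors' FPKM) and an adjusted p of 8.71e-04 (adjusted p = 0.253 with an estimated correlation). This call was lost without IgG replicate 2 (median -0.24), on FPKM (adjusted p = 0.758) and on centred FPKM (median -0.40, adjusted p = 0.135). Over all other settings it ran from 6.68e-06 to 0.758. Of 11 genes of the mitochondrial genome, 0 were higher and 4 lower (0 and 4 adjusted over the list alone), with a median of -0.34 (0.33 on the authors' FPKM) and an adjusted p of 0.0423 (adjusted p = 0.655 with an estimated correlation). That call was lost without IgG replicate 1 (median -0.42), without IgG replicate 2 (-0.39) and without input replicate 2 (-0.07), with limma-voom (adjusted p = 0.241), without a filter (0.355) and with the stricter filter (0.0708). Its adjusted p ran from 1.46e-04 to 0.501. Of 40 chromatin regulators, 17 were higher and 0 lower (25 and 1 adjusted over the list alone), with a median of 0.42 and an adjusted p of 1.31e-15 (adjusted p = 0.0609 with an estimated correlation). Kmt2d stood at 1046 ± 68.5 against 437 ± 5.50 CPM (log2 fold change 1.26). Among all tested genes, the median in IgG RIP over input was -0.37 in the lowest of 10 classes by length index and 0.24 in the highest. Chromatin regulators were not matched on length here either. Of 68 histone mRNAs, 9 were higher and 0 lower (10 and 1 adjusted over the list alone), with a median of 0.07 and an adjusted p of 0.122. In the test on the 2 groups alone the genes higher and lower were 1 and 16 for ribosomal proteins, 0 and 2 for oxidative phosphorylation, 0 and 4 for translation factors, 0 and 3 for the mitochondrial genome, 14 and 0 for chromatin regulators and 7 and 0 for histones. Fry alone passed mitochondrial ribosomal proteins (adjusted p = 0.0123), meiosis (0.0313) and apoptosis and p53 (0.0313) in the lower direction and Wnt, Notch and TGF-beta (0.0156) in the higher. It did not pass the mitochondrial genome (0.159).

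In this comparison 505 genes were higher and 591 lower in IgG RIP (edgeR quasi-likelihood test, Benjamini-Hochberg), 141 and 254 at least 2-fold, and 142 and 141 share a locus span. The libraries did not overlap in 53.8% of genes, where chance gives 33.3%. The test on the 2 groups alone called 124 and 137, all of them among the calls of the pooled test. Without IgG replicate 1 the counts were 2591 and 2999, without IgG replicate 2 they were 2379 and 2852, without IGF2BP1 replicate 1 they were 98 and 108, and without IGF2BP1 replicate 2 they were 102 and 111. Without input replicate 1 or input replicate 2 edgeR called 0 and 0, while with all 6 libraries 3201 genes had an unadjusted p under 0.05 and DESeq2 called 540 and 552. On the authors' FPKM the median gene lay 0.56 higher in IgG RIP and the split was 2870 higher and 144 lower.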

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

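Among the other settings, 4 were chosen after seeing the data: weights per group, the authors' FPKM uncentred and centred, and the test of genes sharing no locus span. Of the results for named genes, 181 kept their direction and side of the threshold with DESeq2-style size factors, 180 without a composition factor, 181 with the stricter filter and 176 with DESeq2, where 3 fell short of it. With only the 2 groups compared 124 did and 56 fell short, and without 1 IGF2BP1 or input library between 39 and 45 did. With the stricter filter 4 lists were called against input, and limma-voom called 332 genes higher in IgG RIP than in input; the cause was not tested. With only the 2 groups compared, 37 genes were higher and 107 lower against IgG RIP, 1925 and 2169 against input, 124 and 137 for IgG RIP against input, and 22 higher than in both controls. Igf2bp1 over input (0.27) then passed the threshold, as each fit holds the spread of its own 2 groups. With the replicate number as a block, 253 genes were higher against IgG RIP and 43 higher than in both controls. No pairing was detected, as the deviations of like-numbered libraries had correlations of -0.00386, 0.00241 and 0.00946. These cannot exclude pairing, since IGF2BP1 RIP and input lie near counting noise (spread index 1.73 and 1.32), which would hide it. The block also ended the call of the mitochondrial genome in IgG RIP against input (adjusted p = 0.141, from 1.46e-04 to 0.501 over its settings). With weights per group, 226 genes were higher and 7 lists called against IgG RIP, 1947 were higher and 2199 lower against input, 158 were higher than in both controls, and Igf2bp1 over input (0.27) passed. With only genes sharing no locus span, 7 lists were called against IgG RIP; the cause was not tested. At a fold change of at least 2, the genes higher and lower were 139 and 226, 24 and 222, and 141 and 254 in the 3 comparisons, and 2 were higher than in both controls.

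The totals of the authors' FPKM ran with depth, from 252152 in input replicate 1 to 423117 in IGF2BP1 replicate 2. On this FPKM the median gene moved by 0.11, 0.68 and 0.56 in the 3 comparisons, which by itself moves genes toward higher. It gave 229 higher and 134 lower against IgG RIP, 3248 and 69 against input, 2870 and 144 for IgG RIP against input, and 171 higher than in both controls. Igf2bp1 over input was 1.35 and passed. The translation factors turned to 0.29 in IgG RIP against input. Genes that changed sign against input include Dazl 0.36, Sparc 0.37, Mki67 0.22, Mdm2 0.42, Pmaip1 0.026, Apc 0.19, Kif5b 0.23, Tpt1 0.22, Eif1 0.059, Suz12 0.21, Kmt2a 0.29, Ssr1 0.37, Idi1 0.11 and Insig1 0.36. These 14 lie below the shift of the median gene. With each library centred, 168 were higher and 135 lower against IgG RIP with 2 lists called, 15 and 75 against input, 121 and 312 for IgG RIP against input with 3 lists called, and 5 were higher than in both controls; Igf2bp3 over input was -0.0061. Why fewer genes passed was not tested.

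Leaving out 1 library at a time, the lone library was assumed to vary like the other groups. Against IgG RIP the genes higher ran from 8 to 2980, the genes lower from 38 to 2681 and the lists called from 2 to 5. Against input they ran from 1 to 2021, from 14 to 2153 and from 6 to 9. For IgG RIP against input they ran from 0 to 2591, from 0 to 2999 and from 3 to 5. The 0 is from edgeR without input replicate 1 or 2, while with all libraries 3201 genes had an unadjusted p under 0.05 and DESeq2 called 540 and 552. The genes higher than in both controls ran from 1 to 802. The highest counts of genes come without an IgG library, as the model then holds no difference between IgG libraries. Igf2bp1 ran from -0.038 to 0.15 over IgG RIP and from 0.23 to 0.34 over input, and Igf2bp3 from -0.12 to 1.53 and from -0.0060 to 0.080. DESeq2 gave no test of lists. Depth limits genes with few fragments: a count of 0 allows up to between 1.06 and 1.86 CPM.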

Other observations

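Of the tests below, those of transcript length, of loss shared with IgG RIP and of KEGG pathways were chosen after the results were seen. The 2 IgG libraries differ widely, with a spread index of 14.2. Cells of another type in 1 IgG library stay open: immune, blood and endothelial markers (median log2 ratio of IgG 1 to IgG 2 of -0.31, Lyz2, picked after its values were seen, at 6320 and 7836 fragments) lie at percentile 10.21 of abundance-matched lists and fibroblast markers (-0.13) at percentile 11, but the immune interval of -0.505 to 0.538 is too wide to exclude a shift as large as that of the typical gene (0.51), so the bound set beforehand was too weak. The mean of the immune list relative to input is -1.08 in IgG 1 and 0.09 in IgG 2. A spread from few captured molecules that were then amplified may be the source, since the index stays nearly level across abundance (slope 0.05108, bootstrap interval 0.0126 to 0.0979, where 0.5 or more would have argued against it). No biological explanation was tested.

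Cytosolic ribosomal protein mRNAs are lower in IGF2BP1 RIP than in input. Genes with a low length index (count over FPKM) are lower in general, with a median of -0.53 in the lowest of 10 classes, but the list median of -1.004 lies below lists matched on this index (-0.805 to -0.434), so length is argued against as the whole cause. A loss shared by any pull-down is argued against as the whole cause by the difference between IGF2BP1 RIP and IgG RIP (fry p = 0.00495), although camera with an estimated correlation gives an adjusted p of 0.196 for that difference. Fry does not compare the list with other genes, and genes of the lowest length class had a median of -0.14 against IgG RIP. No lists matched on length were drawn for that comparison, so a shared loss together with length is not excluded. Part of the loss may be shared, as the IgG libraries lie at -0.50 and -0.71. Binding by IGF2BP1 was not tested.

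Replication-dependent histone mRNAs are lower in IGF2BP1 RIP than in both controls. Against input, their median of -1.04 lies inside lists matched on the length index (-1.14 to -0.660), so short transcripts may account for that part. Against IgG RIP, the median of -1.005 lies below matched lists (-0.593 to -0.117), which argues against length there. A different split of fragments between near-identical copies is argued against, as the sum over 69 genes is also lower, by a log2 ratio of -0.74 against input and -1.06 against IgG RIP (5587 and 5580 CPM in IGF2BP1 RIP, 10892 and 12467 in IgG RIP, 9545 and 9107 in input). The lack of a poly(A) tail and the binding of IGF2BP1 were not tested.

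Of 232 KEGG pathways, several passed camera at the preset correlation in IGF2BP1 RIP against IgG RIP. Higher were carbon metabolism (88 genes, 9 higher and 0 lower, median 0.30, adjusted p = 0.00201), amino acid biosynthesis (54, 4 and 0, 0.33, 0.00207), the citrate cycle (29, 4 and 0, 0.38, 0.00207), unsaturated fatty acid synthesis (17, 3 and 0, 0.67, 0.00248), fatty acid elongation (16, 3 and 0, 0.60, 0.00683), fatty acid metabolism (41, 4 and 0, 0.57, 0.0101), fatty acid degradation (32, 3 and 0, 0.53, 0.0148), basal transcription factors (41, 8 and 0, 0.20, 0.0150) and DNA replication (35, 3 and 0, 0.27, 0.0428). Lower were the ribosome (129, 5 and 34, -0.33, 5.11e-09) and the sets named systemic lupus erythematosus (91, 2 and 28, -0.81, 1.07e-13) and alcoholism (135, 1 and 29, -0.39, 3.23e-07). With an estimated correlation none of these passed in camera, with adjusted p from 0.690 to 0.866. The counts of genes are from the pooled test. The overlap of these pathways with the lists above, as of the ribosome with ribosomal proteins, was not counted. The pathways therefore cannot be read as results apart from those of the lists.

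Some genes had 0 fragments in both IgG libraries and at least 50 in each of the other 4. They were Dhx38 (281 and 300 in IGF2BP1 RIP, 133 and 138 in input), Lin9 (66 and 75, 61 and 63) and Mea1 (95 and 108, 53 and 72), which shares a locus span. They were picked after their values were seen, and none was called higher than in both controls. The fragments are not scaled to depth: 1 fragment is 0.356 and 0.353 CPM in IGF2BP1 RIP and 0.620 and 0.592 CPM in input. Counts of IGF2BP1 RIP and input are therefore not comparable as they stand. With a lower limit on the other 4 libraries, genes at 0 in both libraries of a group numbered 8 for IgG RIP and 0 for each of the other groups.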
